A study of Mus musculus with 9 samples.

How the data were processed

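RNA was measured in 9 libraries of mouse embryonic cortical neurons, 3 for each of 3 treatments. The treatments were a non-charged peptide amphiphile (PA), a nanostructure charged with Na+ ions (Na+ ICN) and one charged with K+ ions (K+ ICN). Per the labels, a stock of 5 mM was used at 200 µM, 80 µl was placed on the cells, and 50% of the medium was changed at 48 h. The series design gives harvest at 72 h and 3 biological replicates per condition. The labels do not say whether replicates came from separate animals or dissections, so p-values measure the spread between these cultures. Polyadenylated RNA was made into stranded libraries and read from one end.

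The authors deposited raw counts as whole numbers for 40773 gene symbols, with no rows lacking a name. Per the submitters' processing notes, Trim Galore, STAR and RSEM were used with the mouse build GRCm38, with no versions given. Whether the deposited counts come from STAR or are rounded RSEM estimates, the gene annotation, and the strand setting are not given in the sources used here. Genes that share reads with close copies or overlap another gene are therefore uncertain, among them the class I genes H2-K1 and H2-D1 and the ribosomal proteins, which have many pseudogenes. Library totals ranged from 17924988 to 22906950 counts. Pairs of replicates differed by more than counting noise, with a chi-square per degree of freedom between 3.26 and 4.31, so each library was kept as its own replicate.

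Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes with enough counts by filterByExpr with a count minimum of 10 were kept, which left 15183 genes holding 99.93% of all counts. Libraries were scaled by TMM, a robust quasi-likelihood model was fitted to all 9 libraries so that the groups shared their spread, and 3 comparisons were tested. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Fold changes are given on the log2 scale with a standard error, and levels as CPM (counts scaled to the library total) with the SD over 3 libraries. The common dispersion corresponded to a coefficient of variation of 5.67% between replicates.

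In total, 35 gene lists with 1135 entries were fixed before the data were examined, and 5 entries, older symbols, were not found. The 34 lists with at least 5 tested genes were tested with limma 3.58.1 (camera on voom values, preset correlation 0.01), adjusted over 34 lists per comparison. The same lists were tested with a correlation estimated from the data and with fry. Only 1 red blood cell gene was tested, so that list has no test. Named genes were chosen by a rule fixed at the same time. It takes the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold. These needed a mean of at least 5 CPM, groups that do not overlap, and a symbol that is not a predicted gene. The rule adds up to 4 members of each described list with the smallest p, and 10 genes named in every comparison. Some genes that the rule takes are not reported here.

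The gene test was tried on simulated counts for 15183 genes with 200 changed genes. For Na+ ICN against PA it recovered 32.8% of genes changed 1.2-fold, 62.7% of those changed 1.5-fold and 73.8% of those changed 2-fold, and 3.48% of its calls were unchanged genes. For K+ ICN against PA the shares were 42.4%, 61.2% and 78.5%, with 4% unchanged genes among the calls. For K+ ICN against Na+ ICN they were 31.3%, 71.6% and 90.8%, with 4.48%. Simulated genes took the trended dispersion, without spread between genes of like level, and fewer were changed than were called in the data. These shares may therefore differ in the data. The list test, tried on simulated genes that varied independently, called no list that had not been shifted.

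Alternatives were DESeq2 1.42.0, DESeq2 size factors or upper-quartile factors in edgeR, limma voom, no low-count filter, a filter of 1 CPM in 3 libraries, a fit to the 6 libraries compared, a fit with the replicate number as a term, an added 2-fold threshold, and leaving out each library in turn. Both ICN groups were compared with the same PA libraries. For this reason, 50 simulations of 3 unchanged groups gave the overlap and correlation that shared controls produce when no gene changes. They were first drawn with the PA libraries as observed and the ICN groups around the mean of those, with trended dispersion, which removes the error of the shared controls. After that result was seen, all 9 libraries were drawn from one mean, and the dispersion was changed to the tagwise one. Length and GC content came from the longest transcript per symbol in GENCODE vM21, which covered 93.9% of the genes tested. Gene positions are from the GRCm38.p6 RefSeq annotation, in which 98.7% of the tested symbols were found. No sample and no value column was left out.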

Results

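The data are gene counts from 9 cultures of mouse embryonic cortical neurons, 3 each with the non-charged peptide amphiphile (PA), the Na+ ion-charged nanostructure (Na+ ICN) and the K+ ion-charged nanostructure (K+ ICN). Peptide amphiphiles are short peptides with a lipid tail that assemble into fibres. PA libraries held 18532789 to 22906950 counts, Na+ ICN libraries 17924988 to 20640622 and K+ ICN libraries 20573886 to 21914112. The first principal component held 20.6% of the variance and separated PA from both ICN groups, and the second held 14.8% and separated K+ from Na+. Mitochondrially encoded genes took 4.27% ± 0.101 of the counts in PA (SD, n = 3), 5.32% ± 0.107 with Na+ ICN and 5.03% ± 0.137 with K+ ICN.

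The first comparison asked which genes differ 72 h after Na+ ICN treatment from the non-charged control. With Na+ ICN, messenger RNAs of the mitochondrial genome and astrocyte marker genes rose, and genes of GABAergic neurons and GABA receptors fell. The cytochrome c oxidase subunit mt-Co3 rose 1.43-fold (log2 fold change 0.51, SE 0.023, edgeR adjusted p = 1.92e-22), from 3948 ± 41.6 to 5633 ± 174 CPM (SD, n = 3). Apoe, the lipid carrier made mainly by astrocytes in brain (chromosome 7, 19696244 to 19701310, GRCm38), rose 1.42-fold (log2 0.51, SE 0.042, edgeR adjusted p = 8.88e-13). Gad1, which makes GABA from glutamate (chromosome 2, 70561303 to 70602014), fell to 0.807 of the PA level (log2 -0.31, SE 0.035, edgeR adjusted p = 7.37e-09). Bdnf, a neurotrophin, and Fos, an immediate early transcription factor, did not pass (log2 -0.13, SE 0.067, adjusted p = 0.214, and 0.045, SE 0.073, adjusted p = 0.774, edgeR). Of 29 immediate early genes 3 rose and 1 fell, and of 29 late activity genes 1 rose and 4 fell. Camera called neither list (adjusted p = 0.707 and 0.111). Fry called the late activity list as lower (adjusted p = 0.03) but not the immediate early list (adjusted p = 0.619).

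Of 13 mitochondrial protein-coding genes, 11 rose, 12 when adjusted over the list alone, with a median log2 fold change of 0.35 (camera adjusted p = 1.48e-36, and adjusted p = 0.0122 with an estimated correlation). Of 22 astrocyte genes tested, 14 rose and none fell, 15 adjusted over the list alone (median 0.25, camera adjusted p = 9.78e-14, adjusted p = 0.0325 with an estimated correlation). Sparcl1, a secreted synapse-modulating protein, rose 1.38-fold, the chaperone Clu 1.32-fold, and Gfap, the astrocyte intermediate filament, 1.39-fold. Of 29 GABAergic genes, 15 fell and 1 rose, as when adjusted over the list alone (median -0.16, camera adjusted p = 4.23e-10, adjusted p = 0.0103 with an estimated correlation). They included the receptor subunits Gabrg1 (log2 -0.65, SE 0.099) and Gabra2 (log2 -0.21, SE 0.033) and the metabotropic receptor Gabbr2 (log2 -0.26, SE 0.039).

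Among genes that the naming rule admits, the largest rises were in Gipr, the receptor for gastric inhibitory polypeptide (2.49-fold), Kcns1, a potassium channel modifier subunit (2.33-fold), the nucleoside transporter Slc29a1 (2.15-fold) and the proteoglycan Bgn (2.14-fold). Rasip1 rose 2.04-fold, the myosin light chain Myl9 2.03-fold, the long non-coding RNA Neat1 1.99-fold and Tcfl5 1.98-fold. Txnip, a regulator of glucose uptake and redox state, had the largest fall among them, to 0.374 of PA (log2 -1.42, SE 0.18, edgeR adjusted p = 9.37e-08). The secreted phosphoprotein Spp1 fell to 0.522, Zfp965 to 0.62, Ndnf to 0.632, Zfhx2 to 0.639 and Gabrg1 to 0.639 of PA. Myh8 (0.593) and Lrguk (0.635) passed with all libraries. Myh8 did not pass without Na+ ICN replicate 2 (adjusted p = 0.102), nor Lrguk without PA replicate 2 (adjusted p = 0.0529).

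Genes for ribosomal proteins rose in 43 of 74 cases, 56 adjusted over the list alone, and none fell (median 0.15). Rpl12 rose 1.28-fold. Their list passed camera (adjusted p = 5.98e-30) but not with an estimated correlation (adjusted p = 0.0789). Of 44 presynaptic genes 14 fell, 17 adjusted over the list alone and 9 with upper-quartile scaling, among them the calcium sensor Syt1 (log2 -0.28, SE 0.028) and the active zone protein Bsn (log2 -0.18, SE 0.033), and 2 rose, including Syn3 (log2 0.37, SE 0.035). That list gave adjusted p = 0.0786 with an estimated correlation. Of 32 cholesterol genes 10 rose, 13 adjusted over the list alone, including Hmgcs1 (1.13-fold), and of 27 neural progenitor genes 10 rose, also 13 adjusted over the list alone, including the intermediate filament Vim (1.24-fold), with adjusted p = 0.0923 and 0.0789 with an estimated correlation.

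Markers of other cells and stress moved in part. Of 14 endothelial and mural genes 4 rose, 6 adjusted over the list alone, including the contractile proteins Tagln (1.94-fold) and Acta2 (1.66-fold), and of 19 fibroblast genes 6 rose and 2 fell, Col1a1 rising 1.66-fold and the progenitor receptor Pdgfra falling to 0.689. These lists gave adjusted p = 0.073 and 0.0776 with an estimated correlation. Camera also called as higher cell division (5 of 38 rose, 7 adjusted over the list alone), extracellular matrix (12 of 44 rose and 3 fell, 18 and 4 adjusted over the list alone), interferon-stimulated genes (5 of 18 rose, 8 adjusted over the list alone), p53 and apoptosis (3 of 31 rose) and axon injury (3 of 18 rose and 2 fell). With an estimated correlation these gave adjusted p = 0.14, 0.0789, 0.073, 0.073 and 0.0995. It called as lower potassium channels (9 of 50 fell, 2 rose), sodium channels (1 of 9 fell), glutamate receptors (5 of 23 fell, 2 rose), postsynaptic genes (7 of 36 fell) and nuclear-encoded respiratory chain genes (3 of 56 fell, 0 adjusted over the list alone and 0 with upper-quartile scaling). The same test with an estimated correlation gave adjusted p = 0.0913, 0.0964, 0.14, 0.073 and 0.429. Sodium channels lost the call without PA replicate 1 (0.0546), glutamate receptors without PA replicate 2 (0.0863) and axon injury without PA replicate 3 (0.0546) or Na+ ICN replicate 1 (0.0675). The other 15 lists did not pass camera, with adjusted p from 0.053 to 0.936. Among these, the cation transport and oligodendrocyte lists had a median below 0 and a mean above 0 (-0.023 and 0.047, -0.054 and 0.21), with camera pointing up. The excitatory and the lysosome and lipid efflux lists also differed in sign between median and mean (0.0037 and -3.4e-04, -0.050 and 0.0035).

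In all, 1648 of 15183 genes passed, 855 higher and 793 lower, with a median fold of 1.19 among them, and 3569 had an unadjusted p under 0.05. The groups did not overlap in 26.7% of genes, where chance gives 10%. Camera called 19 of 34 lists, 12 up and 7 down, and 3 held with an estimated correlation. Upper-quartile scaling changed the split to 1042 higher and 552 lower. Without PA replicate 3 the count was 1079, and without Na+ ICN replicate 2 it was 1089.

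**Figure D1:**
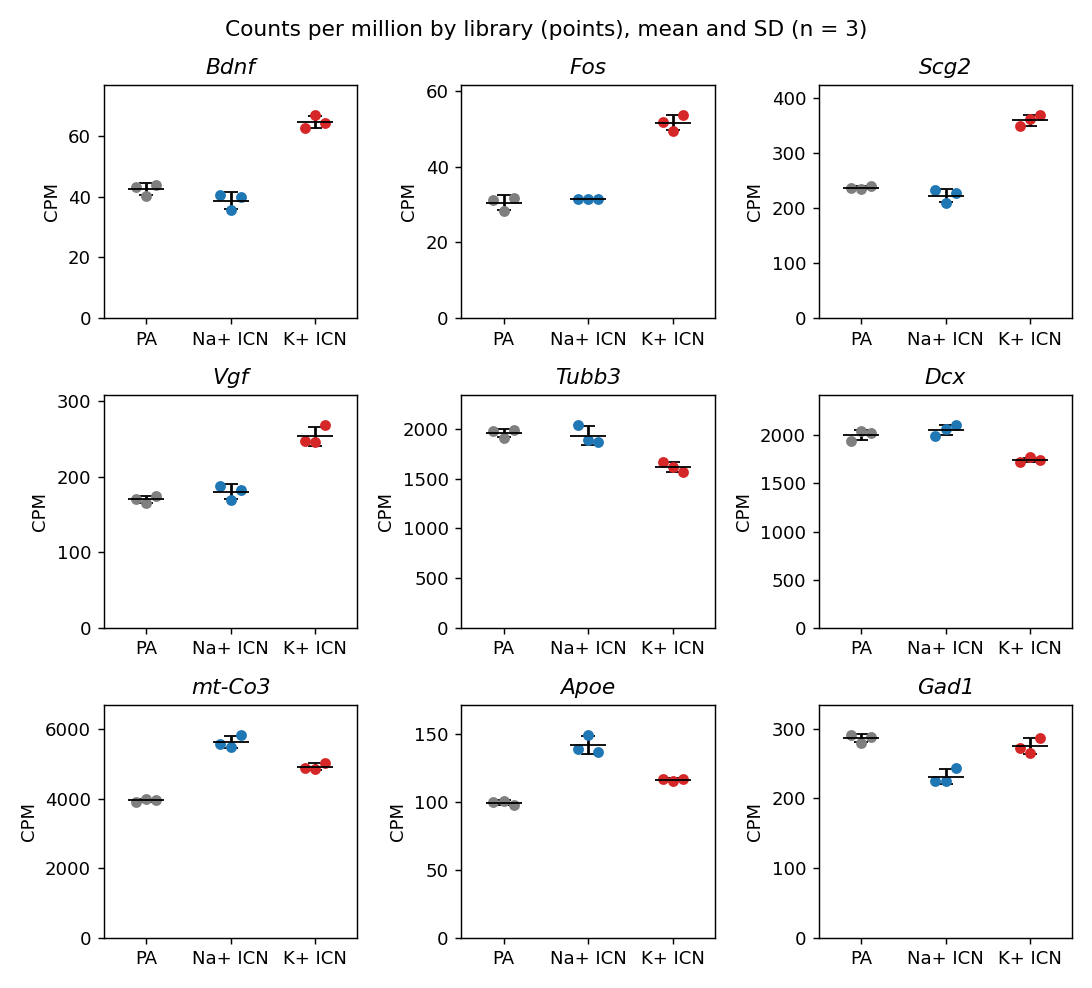
Levels in CPM (vertical axes, from 0) of 9 genes in each of 9 libraries, by treatment. Points are libraries and bars show the mean and SD (n = 3); Bdnf was at 42.4 CPM in PA, 38.7 with Na+ ICN and 64.5 with K+ ICN.

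The second comparison asked the same of K+ ICN. With K+ ICN, activity-induced genes rose and genes of the neuronal cytoskeleton and of axon growth fell. Bdnf (chromosome 2, 109674700 to 109727043) rose 1.52-fold (log2 0.60, SE 0.065, edgeR adjusted p = 7.02e-10), from 42.4 ± 2.02 to 64.5 ± 2.05 CPM (SD, n = 3). Fos (chromosome 12, 85473890 to 85477274) rose 1.69-fold (log2 0.76, SE 0.07, edgeR adjusted p = 1.09e-11). Tubb3, the neuronal tubulin (chromosome 8, 123411553 to 123422015), fell to 0.825 of PA (log2 -0.28, SE 0.028, edgeR adjusted p = 2.64e-09). Arc and Dlg4 did not pass (log2 -0.15 and 0.064).

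Of 29 immediate early genes 12 rose and none fell, 15 adjusted over the list alone (median 0.28, camera adjusted p = 4.76e-09, adjusted p = 0.0266 with an estimated correlation). They included the nuclear receptor Nr4a3 (1.41-fold), the activity-dependent factor Npas4 (1.62-fold) and the matricellular protein Ccn1 (1.76-fold). Of 29 late activity genes 12 rose and 1 fell, as when adjusted over the list alone (median 0.32, camera adjusted p = 2.33e-08, adjusted p = 0.0175 with an estimated correlation). The secretory granule protein Scg2 rose 1.52-fold, the neuropeptide precursor Vgf 1.49-fold and Rgs2, a brake on G protein signalling, 1.43-fold.

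Of 49 genes of neurite growth and cytoskeleton 28 fell and 1 rose, 31 and 1 adjusted over the list alone (median -0.097, camera adjusted p = 4.10e-13, adjusted p = 0.0175 with an estimated correlation). Besides Tubb3, the semaphorin co-receptor Plxna4 fell to 0.833, the microtubule proteins Dcx to 0.87 and Map1b to 0.891, and Map2 to 0.893 of PA. Of 36 postsynaptic genes 13 fell and 2 rose, 15 and 4 adjusted over the list alone (median -0.084, camera adjusted p = 4.49e-04, adjusted p = 0.0266 with an estimated correlation), including the scaffolds Shank1 (0.768) and Dlgap1 (0.826) and the adhesion protein Nlgn1 (0.777). Of 30 excitatory cortical genes 8 fell and 3 rose, 11 and 3 adjusted over the list alone, with adjusted p = 0.0626 with an estimated correlation. Among them Mef2c, a neuronal transcription factor, fell to 0.671 (log2 -0.58, SE 0.027, edgeR adjusted p = 1.24e-21).

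Genes of the extracellular matrix rose in 22 of 44 cases and fell in 6, 26 and 7 adjusted over the list alone (median 0.26, camera adjusted p = 1.23e-05, adjusted p = 0.0266 with an estimated correlation). The collagen-binding Sparc rose 1.49-fold and Thbs1 1.56-fold, and the proteoglycan Vcan fell to 0.807. Of 19 fibroblast genes 9 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.41, adjusted p = 0.0266 with an estimated correlation), with Col1a1 at 1.97-fold. Interferon-stimulated genes rose in 7 of 18 cases, 9 adjusted over the list alone (median 0.62, adjusted p = 0.0266 with an estimated correlation), including the antigen presentation genes H2-K1 (2.3-fold), H2-D1 (1.51-fold) and B2m (1.69-fold). Mitochondrial messenger RNAs rose in 9 of 13 cases, 9 with 1 lower adjusted over the list alone (median 0.16, adjusted p = 0.0322 with an estimated correlation), mt-Co1 by 1.26-fold. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, chosen after their values were seen, fell (log2 -0.14, SE 0.03, and -0.23, SE 0.036, edgeR adjusted p = 4.6e-04 and 8.03e-05). Of 22 astrocyte genes 12 rose and 1 fell, 14 and 3 adjusted over the list alone, and of 38 cell division genes 13 rose, 24 adjusted over the list alone, Top2a by 1.23-fold. These gave adjusted p = 0.0626 and 0.0749 with an estimated correlation.

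Among genes that the rule admits, the largest rises were in Gipr (3.06-fold), Rgs13 (2.69-fold), the matricellular protein Ccn2 (2.68-fold), Slc29a1 (2.42-fold), the cGMP-dependent kinase Prkg2 (2.35-fold), Bgn (2.34-fold), Tagln (2.33-fold) and the relaxin receptor Rxfp1 (2.32-fold). Txnip fell to 0.381 of PA, Tafa1 to 0.501, the retinoic acid enzyme Aldh1a3 to 0.528, the synapse organiser Cbln2 to 0.554, the arrestin-like Arrdc4 to 0.557, the cation channel Trpc5 to 0.566, Gabrg1 to 0.591 and Tmtc1 to 0.594. The stress response list had 16 of 34 genes higher and 3 lower, 17 and 3 adjusted over the list alone, with Atf5 at 1.54-fold and Atf4 at 1.22-fold (adjusted p = 0.0626 with an estimated correlation). Camera also called neural progenitor genes (11 of 27 rose, 1 fell), endothelial and mural genes (3 of 14 rose) and ribosomal proteins (19 of 74 rose, 20 adjusted over the list alone) as higher. It called sodium channels (4 of 9 fell), glutamate receptors (9 of 23 fell, 3 rose) and nuclear-encoded respiratory chain genes (3 of 56 fell, 0 adjusted over the list alone) as lower. With an estimated correlation these gave adjusted p = 0.155, 0.0607, 0.317, 0.124, 0.16 and 0.423. Sodium channels lost the call without PA replicate 1 (0.059) or K+ ICN replicate 1 (0.0904) and with the CPM filter (0.0502), and glutamate receptors without PA replicate 2 (0.0587). Syn1 rose 1.06-fold at an adjusted p of 0.0464, a call that ended with DESeq2 size factors, DESeq2 itself and no low-count filter, and with PA replicate 2 or 3 or any K+ ICN library left out (adjusted p from 0.0528 to 0.289).

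In all, 2403 genes passed, 1237 higher and 1166 lower, and 4236 at an unadjusted p under 0.05. The groups did not overlap in 32% of genes, where chance gives 10%. Camera called 19 of 34 lists, 12 up and 7 down, and 8 held with an estimated correlation. Upper-quartile scaling changed the split to 1440 higher and 902 lower. With a 2-fold threshold added to the main test, 107 genes were higher and 12 lower.

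**Figure D2:**
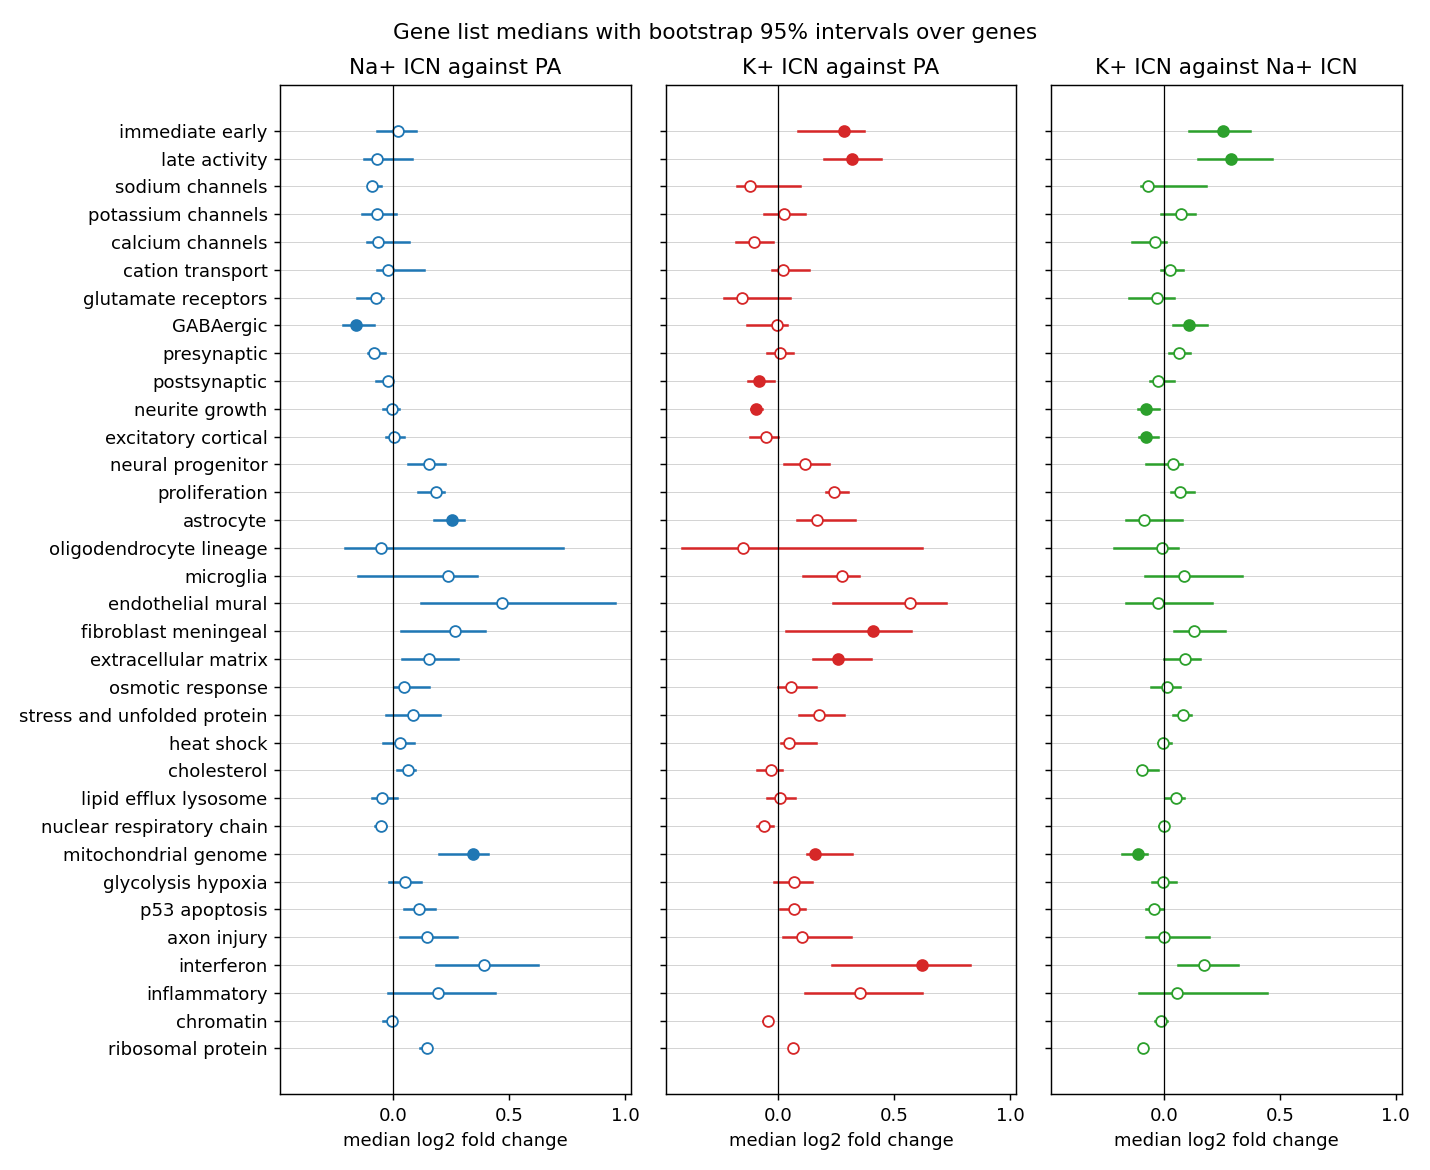
Median log2 fold change (horizontal axes) of 34 gene lists in the 3 comparisons, with bootstrap 95% intervals over genes. Filled points are lists with an adjusted p under 0.05 with an estimated correlation, 3 for Na+ ICN against PA, 8 for K+ ICN against PA and 6 for K+ ICN against Na+ ICN.

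The third comparison set the 2 ions against each other directly. Activity-induced genes were higher with K+ than with Na+, and genes of neurite growth, excitatory cortical identity and the mitochondrial genome were lower. Bdnf was 1.67-fold higher (log2 0.74, SE 0.065, edgeR adjusted p = 7.94e-12) and Fos 1.64-fold higher (log2 0.71, SE 0.07, edgeR adjusted p = 1.65e-10). Rgs4, which limits G protein signalling (chromosome 1, 169741477 to 169747642), was 1.72-fold higher (log2 0.78, SE 0.043). Sox11, a factor of immature neurons (chromosome 12, 27334268 to 27342718), was lower, at 0.797 of the Na+ level (log2 -0.33, SE 0.028, edgeR adjusted p = 4.94e-12).

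Of 29 late activity genes 12 were higher and none lower, 13 adjusted over the list alone (median 0.29, camera adjusted p = 1.08e-15, adjusted p = 0.00269 with an estimated correlation), with Scg2 at log2 0.69, Rgs2 at 1.52-fold and Vgf at 1.41-fold. Of 29 immediate early genes 10 were higher, 13 adjusted over the list alone (median 0.25, adjusted p = 0.0189 with an estimated correlation), with Nr4a3 at 1.39-fold and Nr4a1 at 1.44-fold. GABAergic genes were higher in 11 of 29 cases, 13 with 1 lower adjusted over the list alone (median 0.11, adjusted p = 0.0106 with an estimated correlation), including Gad1 (1.19-fold) and Gabrg3 (1.37-fold). Potassium channels were higher in 10 of 50 cases and lower in 1, 13 and 2 adjusted over the list alone, with Kcnk9 at 1.47-fold and Kcna1 at 1.51-fold, and presynaptic genes in 12 of 44 with 2 lower, 17 and 3 adjusted over the list alone. These gave adjusted p = 0.0555 with an estimated correlation. Camera did not call the GABAergic, potassium channel or presynaptic list for K+ ICN against PA (adjusted p = 0.15, 0.554 and 0.977). Fry called the GABAergic list as lower for K+ ICN against PA (adjusted p = 9.38e-04) and not the other lists (adjusted p = 0.121 and 0.927). In that comparison 3 GABAergic genes rose and 7 fell, 9 potassium channel genes rose and 7 fell, and 10 presynaptic genes rose and 8 fell.

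Neurite growth genes were lower in 23 of 49 cases and higher in 3, 25 and 5 adjusted over the list alone (median -0.077, adjusted p = 0.0106 with an estimated correlation), with Tubb2b at 0.842, Dcx at 0.849 and the axonal adhesion protein Cntn2 at 0.797. Excitatory cortical genes were lower in 8 of 30 cases and higher in 1, 10 and 1 adjusted over the list alone (median -0.075, adjusted p = 0.0259 with an estimated correlation), with Mef2c at 0.81 and Lmo4 at 0.789. Mitochondrial messenger RNAs were lower in 8 of 13 cases, 10 adjusted over the list alone (median -0.11, adjusted p = 0.0296 with an estimated correlation), with mt-Nd3 at 0.813 and mt-Co3 at 0.874. The ribosomal RNAs mt-Rnr1 and mt-Rnr2, chosen after their values were seen, were lower as well (log2 -0.099, SE 0.03, and -0.12, SE 0.036, edgeR adjusted p = 0.0347 and 0.0416). Neither passed without Na+ ICN replicate 1 (0.0905 and 0.0825) or 3 (0.171 and 0.179) or K+ ICN replicate 1 (0.0919 and 0.166) or 2 (0.263 and 0.158), nor did mt-Rnr2 with limma voom (0.193). Cholesterol genes were lower in 11 of 32 cases and higher in 1, 17 and 1 adjusted over the list alone, and ribosomal proteins lower in 13 of 74, 29 adjusted over the list alone, with adjusted p = 0.0555 and 0.202 with an estimated correlation. For K+ ICN against PA, 4 cholesterol genes rose and 6 fell, and camera did not call that list (adjusted p = 0.533). Astrocyte genes were lower in 6 of 22 cases and higher in 1, with Sparcl1 at 0.774 and Apoe at 0.823 (adjusted p = 0.292 with an estimated correlation). That list lost the call without Na+ ICN replicate 2 (0.0686) or 3 (0.0512) or K+ ICN replicate 1 (0.0587). Camera also called as higher cell division (0 of 38 passed), fibroblast genes (1 of 19 rose), extracellular matrix (10 of 44 rose, 2 fell), the stress response (5 of 34 rose, 1 fell) and lysosome and lipid efflux (3 of 40 rose), and as lower calcium channels (3 of 20 fell, 2 rose). With an estimated correlation these gave adjusted p = 0.393, 0.0677, 0.0555, 0.104, 0.104 and 0.195. Cell division lost the call without Na+ ICN replicate 1 (0.297), lysosome and lipid efflux without Na+ ICN replicate 3 (0.0817) or K+ ICN replicate 1 (0.0783), and calcium channels without Na+ ICN replicate 1 (0.0913) or 3 (0.196), K+ ICN replicate 1 (0.134) or 2 (0.0515), and with the CPM filter (0.0681). Median, mean and camera differed in sign for sodium channels, glutamate receptors, progenitor, endothelial and mural, osmotic, heat shock, glycolysis, p53 and axon injury lists, none of which passed.

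Among genes that the rule admits, the largest differences upward were in Rgs13 (2.64-fold), Rxfp1 (2.39-fold), Tmem255a (1.87-fold), Calcrl (1.86-fold), the clock factor Npas2 (1.79-fold), Prkg2 (1.73-fold), Omg (1.72-fold) and Rgs4. Downward they were in Dclk3 (0.538), Tshr (0.573), Tafa1 (0.577), Abca8b (0.614), Gpc5 (0.62), Epha8 (0.653), Slc38a3 (0.661) and Arhgap28 (0.665). Abca8b did not pass without Na+ ICN replicate 2 (adjusted p = 0.149), Epha8 without K+ ICN replicate 2 (adjusted p = 0.0649) or Arhgap28 without Na+ ICN replicate 3 (adjusted p = 0.0549). In all, 999 genes passed, 505 higher and 494 lower, with 2722 at an unadjusted p under 0.05. The groups did not overlap in 22% of genes, where chance gives 10%. Camera called 17 of 34 lists, 10 up and 7 down, and 6 held with an estimated correlation.

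The responses to both ICNs overlapped. In both comparisons with PA, 497 genes were higher and 401 lower, while 33 went in opposite directions. Without PA replicate 3 the shared genes were 597, 354 higher and 243 lower. Of these 33, Kcnk9, Fosl2 and Rgs4 were lower with Na+ and higher with K+, and Sox11 and Tubb2b the reverse, with Tubb2b not passing against PA for Na+ under limma voom (adjusted p = 0.056). Gipr, Slc29a1 and Bgn rose and Txnip and Gabrg1 fell in both. Independent lists of these sizes would share 69.7 higher and 60.9 lower genes, and 50 simulations of unchanged groups with shared controls shared 0.24 and 0.2 on average. Few genes can pass where none is changed, so these simulated counts do not show how many shared genes the controls add. Across genes, which are not independent replicates, the log2 fold changes correlated at 0.611, against 0.508 in those simulations (0.426 to 0.601). Their covariance was 0.0819 against 0.0306, a difference of 0.0514. How these simulations were drawn was changed after a first result was seen, and the form first written gave a correlation of -0.011 and a covariance of -2.45e-04. With 3 PA libraries the controls could not be divided with 2 in each part, so part of the excess may come from the shared controls.

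**Figure D3:**
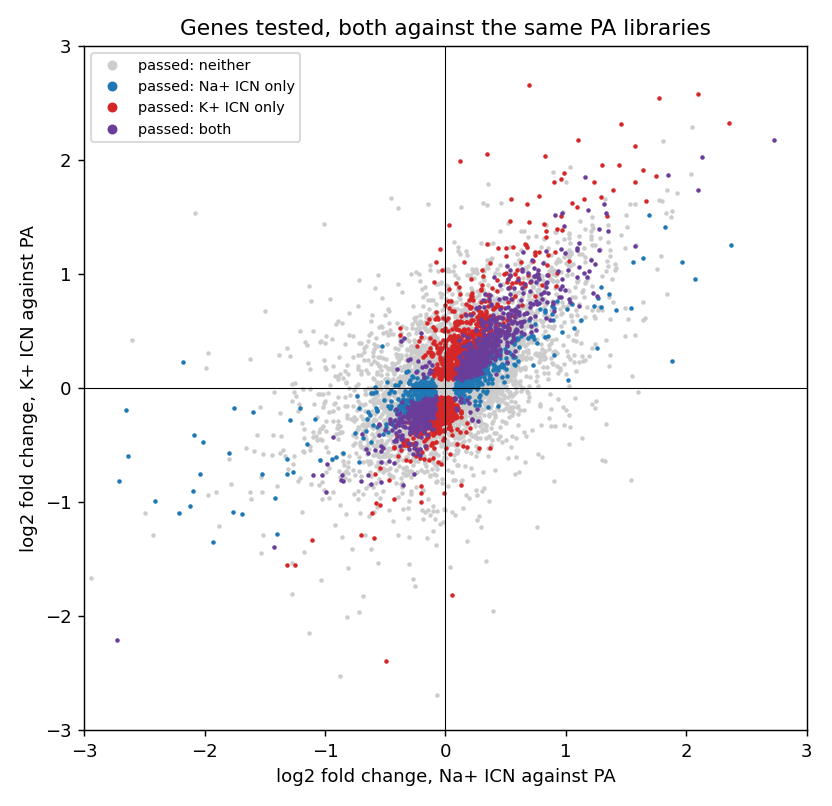
Log2 fold change with Na+ ICN (horizontal) and K+ ICN (vertical), both against the same PA libraries, for 15172 genes, with 11 beyond the axes not drawn. Colours show which tests each gene passed; 898 genes passed both in the same direction.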

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

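The tests of total mitochondrial RNA, of the neuron share and of astrocytes and fibroblasts with K+ were chosen after the results were seen. All tests of patterns were planned once the patterns had been seen, and those of length and GC content, SRF and YAP targets and added activity genes were first written before their own values were seen. For length and GC content, the demand that the lower bound of the list median also lie above the matched sets was added after the values were seen, and it changed the reading of the mitochondrial genes from argued against to open. The counts of lists in other splits with an estimated correlation were added afterwards. Bounds and intervals of list medians come from resampling the genes of a list. They treat these genes as independent and leave out the spread between cultures.

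Effects of Na+ and K+ against PA differed by the direct test of K+ against Na+ in 999 genes. Higher with K+ than with Na+, on the log2 scale, were Bdnf (0.74), Fos (0.71), Kcnk9 (0.55), Slc24a4 (0.49), Ccn1 (0.45), Npas4 (0.44), Cdkn1a (0.44), Acta2 (0.32), Vim (0.26) and Clu (0.24). Lower were Hrk (-0.48), Sox11 (-0.33), Mef2c (-0.30), Apoe (-0.28), Tubb3 (-0.26), Scn3b (-0.24), Ndrg1 (-0.20), mt-Co3 (-0.19), Shank1 (-0.14), Map2 (-0.12), mt-Co2 (-0.11, adjusted p = 0.101 with limma voom) and mt-Co1 (-0.072). The list medians that differed were late activity (0.29), immediate early (0.25), GABAergic (0.11), mitochondrial genome (-0.11), neurite growth (-0.077) and excitatory cortical genes (-0.075). With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes as for lists, 1 of 10 splits, the real one, gave as many. The real splits gave 1648, 2403 and 999 genes and the other splits at most 3, 2 and 3. The real splits called 19, 19 and 17 lists at the preset correlation and other splits up to 10, 14 and 10. With an estimated correlation the real splits called 3, 8 and 6 lists and the other splits 0.

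Activity genes were higher with K+ than with Na+. Transcript length and GC content are argued against as the whole cause, since the highest of 1000 matched sets had a median of 0.12, against 0.29 for the late activity list and 0.15 for its lower bound. By such bounds over genes, more astrocytes are argued against, since the upper bound of their list median was 0.077. More fibroblasts stay open (median 0.13, upper bound 0.26). So do microglia (upper bound 0.34) and endothelial and mural cells (upper bound 0.21). A depolarisation response is a hypothesis that may account for it: 28 further activity genes outside the fixed lists had a median of 0.11, above 99.9% of 10000 expression-matched sets. Camera with an estimated correlation gave p = 0.0273 for them. Gadd45a, named after its values were seen, is on a fixed list and was removed after a first result. With it the median was 0.069 and the percentile 98.4. Only 6 of the 28 passed upward and 1 downward. As they are activity genes again, they cannot tell depolarisation from another inducer. The 22 SRF and YAP targets, genes of contractility and cell tension not planned for this pattern, had a median of 0.13 at percentile 100. Of these, 4 passed upward and 1 downward (camera p = 0.0661 with an estimated correlation). The 2 hypotheses are therefore not told apart.

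Mitochondrial messenger RNAs were higher with Na+ ICN, as were ribosomal protein transcripts at the preset correlation (adjusted p = 0.0789 with an estimated correlation). Matching on length and GC content gave at most a median of 0.11 for ribosomal proteins, against 0.15 with a lower bound of 0.12, a narrow margin. For mitochondrial genes the highest matched median was 0.30, below the list median of 0.35, which met the condition first written against length and GC content, but above its lower bound of 0.20, the condition added later, so they are left open. For Na+ against PA, the upper bounds for the ribosomal RNAs mt-Rnr1 and mt-Rnr2, chosen after their values were seen, reached only 0.016. Counts of these ribosomal RNAs therefore did not rise with the messenger RNAs. The libraries were made from polyadenylated RNA, so these counts may not follow the level of ribosomal RNA. More mitochondrial RNA of every kind is therefore left open. For K+ against Na+, the ribosomal RNAs (-0.099 and -0.12) and the messenger RNAs (median -0.11) were both lower. An effect of the ion treatment, and differences in RNA handling between groups, were not tested.

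Astrocyte, endothelial and mural, fibroblast and cell division lists were called higher by camera with both ICNs at the preset correlation. With an estimated correlation only astrocytes with Na+ and fibroblasts with K+ were. Camera called neither the oligodendrocyte nor the microglia list, but fry called microglia as higher with K+ (adjusted p = 0.0217). With Na+ fry did not call microglia (adjusted p = 0.2525). A lower share of neurons would raise all other cell types alike, and the intervals of the 6 list medians all overlapped (highest lower bound minus lowest upper bound -0.042 with Na+ and -0.065 with K+). The oligodendrocyte and, with Na+, the microglia intervals reached below 0, so a change in cell make-up cannot be told apart from a change within cells. A rise of SRF and YAP targets, genes of contractility and cell tension, is a hypothesis: 22 such genes had medians of 0.29 with Na+ and 0.45 with K+, above all 10000 matched sets, with 10 and 14 of them higher. Fibroblasts and mural cells express these genes too, so this does not separate the explanations.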

How the results depend on the processing

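The upper-quartile scaling of list members and the other forms of the shared-control simulation were chosen after the data were seen. Adding a 2-fold threshold left 82 genes for Na+ ICN against PA (49 higher, 33 lower), 119 for K+ ICN against PA (107 and 12) and 18 for K+ against Na+ (14 and 4), since most changes were small. With an estimated correlation 3, 8 and 6 lists were called in place of 19, 19 and 17. With all libraries kept, the other settings run for gene counts left those within 1.5 times, as did fry, DESeq2 size factors, the CPM filter and the replicate block for list counts. Leaving out 1 library gave 1079 to 1376 genes (Na+ against PA), 1778 to 1954 (K+ against PA), 714 to 885 (K+ against Na+) and 597 to 766 shared genes. It gave 18 to 21, 18 to 22 and 14 to 17 lists. The counts of 1079, without PA replicate 3, and 1089, without Na+ ICN replicate 2, and the overlap of 597, without PA replicate 3, were more than 1.5 times below those with all libraries, and fewer samples were then tested. No named gene or list changed direction while called. The replicate block gave 1825, 2612 and 1165 genes, 1015 shared genes and 19, 20 and 17 lists. Same-numbered samples correlated between -0.0993 and 0.114, 2 of 9 pairs above 0.1, and 4 of 9 libraries correlated best with their own number, so the numbers were not taken to pair the samples. Upper-quartile scaling turned the sign of the neurite growth and chromatin medians (Na+ against PA) and of the GABAergic median (K+ against PA), each within 0.02 of 0, and DESeq2 size factors those of nuclear respiratory chain and axon injury genes (K+ against Na+). Upper-quartile scaling moved these list counts by more than 1.5 times, with the cause not tested. For Na+ against PA, genes that fell went from 14 to 9 (presynaptic), 7 to 3 (lysosome and lipid efflux), 5 to 3 (stress response), 4 to 2 (late activity), 3 to 0 (nuclear respiratory chain) and 2 to 1 (axon injury), and genes that rose from 5 to 8 (neurite growth), 3 to 6 (excitatory), 3 to 5 (p53, and chromatin) and 1 to 3 (heat shock). For K+ against PA, genes that rose went from 2 to 4 (calcium channels, postsynaptic, axon injury) and genes that fell from 6 to 3 (chromatin), 2 to 1 (heat shock, and lysosome and lipid efflux) and 1 to 0 (late activity). DESeq2 size factors moved genes that rose from 2 to 1 (calcium channels, K+ against PA) and 1 to 2 (interferon, K+ against Na+). The simulated covariance of 0.0306 was 0.022 with trended dispersion and, with the PA libraries as observed, -3.91e-04 (tagwise) and -2.45e-04 (trended), forms that remove the shared error by construction. DESeq2 gave no adjusted p for 1769, 886 and 3829 genes under its default filtering, which is set per comparison. Depth may limit genes of low count, which was not tested.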

Other observations

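Several fixed lists outside the main account held changes in single members. With Na+ ICN, 10 of 34 stress response genes rose and 5 fell, Atf5 by 0.58 on the log2 scale (edgeR adjusted p = 6.63e-12) and the serine synthesis enzyme Phgdh by 1.34-fold, with the chaperone Hspa5 at 0.874 of PA (camera adjusted p = 0.053). Of 31 cation transport genes 6 rose and 3 fell with Na+ ICN, and 7 rose and 3 fell with K+ ICN, where the sodium-calcium-potassium exchanger Slc24a4 rose 2.04-fold and the pump subunit Atp1b1 rose by 0.13 on the log2 scale (camera adjusted p = 0.915 and 0.221). Of 25 osmotic response genes 2 rose and 1 fell with Na+ ICN and 5 rose and 2 fell with K+ ICN, with Tsc22d3 higher by 0.50 and 0.49 on the log2 scale and Akr1b3 at 0.828 and 0.794 of PA (camera adjusted p = 0.211 and 0.1). With Na+ ICN, Akr1b3 did not pass without PA replicate 1 (adjusted p = 0.0659) or Na+ ICN replicate 1 (adjusted p = 0.0555). Voltage-gated calcium channels fell in 9 of 20 cases and rose in 2 with K+ ICN. Camera called this list as lower (adjusted p = 0.00841), but not with an estimated correlation (adjusted p = 0.0964).

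With K+ ICN against PA, camera did not call microglia (3 of 19 rose, adjusted p = 0.119), heat shock (3 of 19 rose, 2 fell, 0.372), lysosome and lipid efflux (4 of 40 rose, 2 fell, 0.554), glycolysis and hypoxia (7 of 32 rose, 3 fell, 0.0513), inflammatory (4 of 16 rose, 1 fell, 0.115), chromatin (5 of 49 rose, 6 fell, 0.0622) or oligodendrocyte lineage genes (3 of 15 rose, 1 fell, 0.785). The oligodendrocyte median was -0.15 and its mean 0.11. The 1 red blood cell gene tested, Hba-a1, chosen after its values were seen and with a near-identical copy, had means of 0.701 CPM in PA, 1.43 with Na+ ICN and 2.13 with K+ ICN. It rose with K+ ICN (log2 1.63, SE 0.4, edgeR adjusted p = 0.00291) and did not pass with Na+ ICN (log2 1.05, SE 0.42, edgeR adjusted p = 0.101) or between the ions (adjusted p = 0.467).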
